A study of Mus musculus with 12 samples.

How the data were processed

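Epithelium from the proximal colon of mice was collected in EDTA incubations and lysed in TRIZOL, and non-directional mRNA libraries were made with a NEBNext Ultra kit, per the labels' protocols. The 12 samples form 7 groups: cKO Day 0 (uninjected), Day 1, Day 2, Day 4 and Day 6 with 2 libraries each, and injected WT littermates (floxed Satb2 without deletion) on Day 2 and Day 6 with 1 each. Tamoxifen was given once at 1 mg per 20 g of body weight, per the labels. Groups and days come from the sample labels.

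The authors deposited raw read counts per gene symbol (54735 genes) and a table of normalized counts (21731 genes, all of them in the first table). Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned with STAR to GRCm38, counted with featureCounts in unstranded mode with default settings, and normalized with DESeq2. Versions and the annotation release are not given in the sources used here. The deposited normalized signal equals the raw counts divided by 1 size factor per sample, tested on the values, and served only to recover those factors for an alternative. Another 9 columns of the tables match no sample label and were not used.

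Library totals ranged from 15493808 to 26995580 counts. Replicates differed by more than counting noise (chi-square per degree of freedom 18 to 59.9). This argues only against 1 library deposited under 2 labels, and each library was kept as labelled. The biological coefficient of variation was 24.5%.

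Counts were analysed in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, low counts removed with filterByExpr by group at a minimum count of 10 and a total of 15). All 12 libraries were fitted together with 7 group means and 5 residual degrees of freedom, and 17815 genes were tested. Adjusted p-values are Benjamini-Hochberg over these genes within a comparison, with a threshold of 0.05. Counts of genes with an unadjusted p below 0.05 are given beside the calls. A share of 0.05 of the genes tested would fall there with no change at all. CPM values use TMM-adjusted library sizes. The SE of a log2 fold change is its size divided by the square root of F. A lone WT library is assumed to vary like the other groups. Genes with 0 control counts are given as lower bounds against a floor of 3 counts over the group, which covers counting error only.

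Comparisons were each cKO day against Day 0, cKO Day 2 and Day 6 against WT of the same day, WT against Day 0, consecutive cKO days, any change over the cKO days, and the difference between cKO and WT in their Day 2 to Day 6 change. All comparisons with Day 0 share the same control libraries and hence their chance values. Overlaps were therefore set beside 20 simulated draws and beside independent lists. A permutation test of Satb2 enumerated all 495 splits.

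Gene lists were fixed before the data were examined, with the tests, comparisons and main settings: 28 lists with 364 genes, of which 342 were tested. They were ileal bile acid handling, lipid absorption and lipoproteins, small-intestinal brush-border enzymes, sugar and amino acid transporters, Paneth cell, colonocyte, goblet and deep crypt secretory cell, stem cell and Wnt target, cell cycle, enteroendocrine cell, tuft cell, intestinal transcription factors, Hox genes, epithelial antimicrobial and inflammatory, interferon response and MHC class II, xenobiotic metabolism, p53 target, unfolded protein response, immediate early and heat shock, T cell and intraepithelial lymphocyte, B and plasma cell, myeloid cell, fibroblast, smooth muscle, endothelial cell, enteric neuron and glia, erythroid cell, and sex-linked. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry, each adjusted over the 28 lists within a comparison. Tests of cKO Day 2 against WT Day 2 and of single WT days were added after the data were seen. List medians are also given with members at 0 set at their bound.

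Named genes follow a rule fixed before the data were examined. It takes Satb2, then the 10 highest and 10 lowest log2 fold changes among called genes with a mean CPM of at least 1 and no overlap between groups, leaving out predicted genes. It adds up to 4 members of each list by p, or up to 2 by level where none passed, and any member of the transcription factor, bile acid and sex-linked lists. Naming by size was fixed for the comparisons with Day 0 and for cKO Day 6 against WT Day 6. The fixed rule did not cover the other comparisons, where naming by size was used as well. A gene named by size with 1 to 3 counts in a group was left out of the text. Coordinates are from GENCODE M21 on GRCm38, matched by symbol. Genes of near-identical families can share reads, and without strand information antisense partners cannot be separated.

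Steps were tested on simulated data. For cKO Day 6 against Day 0 (17070 genes), 28% of genes changed by 1 on the log2 scale and 75% of those changed by 2 were recovered, with 8 false calls. For cKO Day 6 against WT Day 6 (17070 genes) the shares were 10% and 62%, with 4 false calls. Alternatives were other normalizations (RLE, upper quartile, the authors' factors), DESeq2 1.42.0, limma voom, no filter, a mean CPM of at least 5, a log2 fold change of at least 1, cKO samples with and without a replicate block, only the groups compared, other control groups, and each library left out in turn. Sex, a posterior Hox score, and leaving out genes of other cell types were added as alternatives after the data were seen. Sex varied within a group only on Day 0 and Day 1, where it followed the replicate number. A fit with sex as a covariate therefore cannot tell sex from any other difference tied to that number.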

Results

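Gene expression was measured by mRNA sequencing in epithelium released with EDTA from the proximal colon of mice. The conditional knockout animals (cKO) carry an inducible deletion of Satb2, a chromatin-binding transcription factor of the colon epithelium. They received a single tamoxifen dose, and tissue was taken on Day 1, 2, 4 or 6, while uninjected cKO mice served as Day 0. Each cKO day had 2 libraries. Injected littermates with intact Satb2 (wild type, WT) gave 1 library on Day 2 and 1 on Day 6. The 12 libraries held 15493808 to 26995580 counts, and 17815 genes were tested. Whether the libraries of a group came from separate animals is not stated for every group, so p-values measure only the spread between these libraries. In the Day 0 and Day 1 groups the replicates differed in sex by Xist and Y-linked transcripts: replicate 1 was female and replicate 2 male. The Day 2 and Day 4 libraries were all female by the same genes, and the Day 6 and WT libraries all male. Within groups, sex thus varied only along with replicate number, so a covariate for sex may also take up other differences between replicates.

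Satb2 itself (chromosome 1, 56793981 to 56978650, minus strand, GRCm38) was lower in every injected cKO library than in every control library. The 8 injected cKO libraries held 161.4 ± 22.6 CPM (counts scaled to 1e6 per library, SD, n = 8, range 135.7 to 190.3). The 2 Day 0 and 2 WT libraries held 243 ± 29.1 CPM (SD, n = 4, range 214.3 to 273.2). The ratio was 66.2% of the control level, a log2 difference of -0.59 (two-sided exact permutation test, p = 0.00202, the smallest that the 495 splits allow, chosen after the values were seen). Day by day against Day 0, the log2 differences were -0.64 on Day 1, -0.50 on Day 2, -0.73 on Day 4 and -0.61 on Day 6, each with an SE of 0.20, and none passed (edgeR adjusted p = 0.848, 0.482, 0.0809 and 0.126). These counts cover the gene as a unit, and the deleted part is not named in the sources used here, so transcripts outside it would still be counted.

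**Figure D1:**
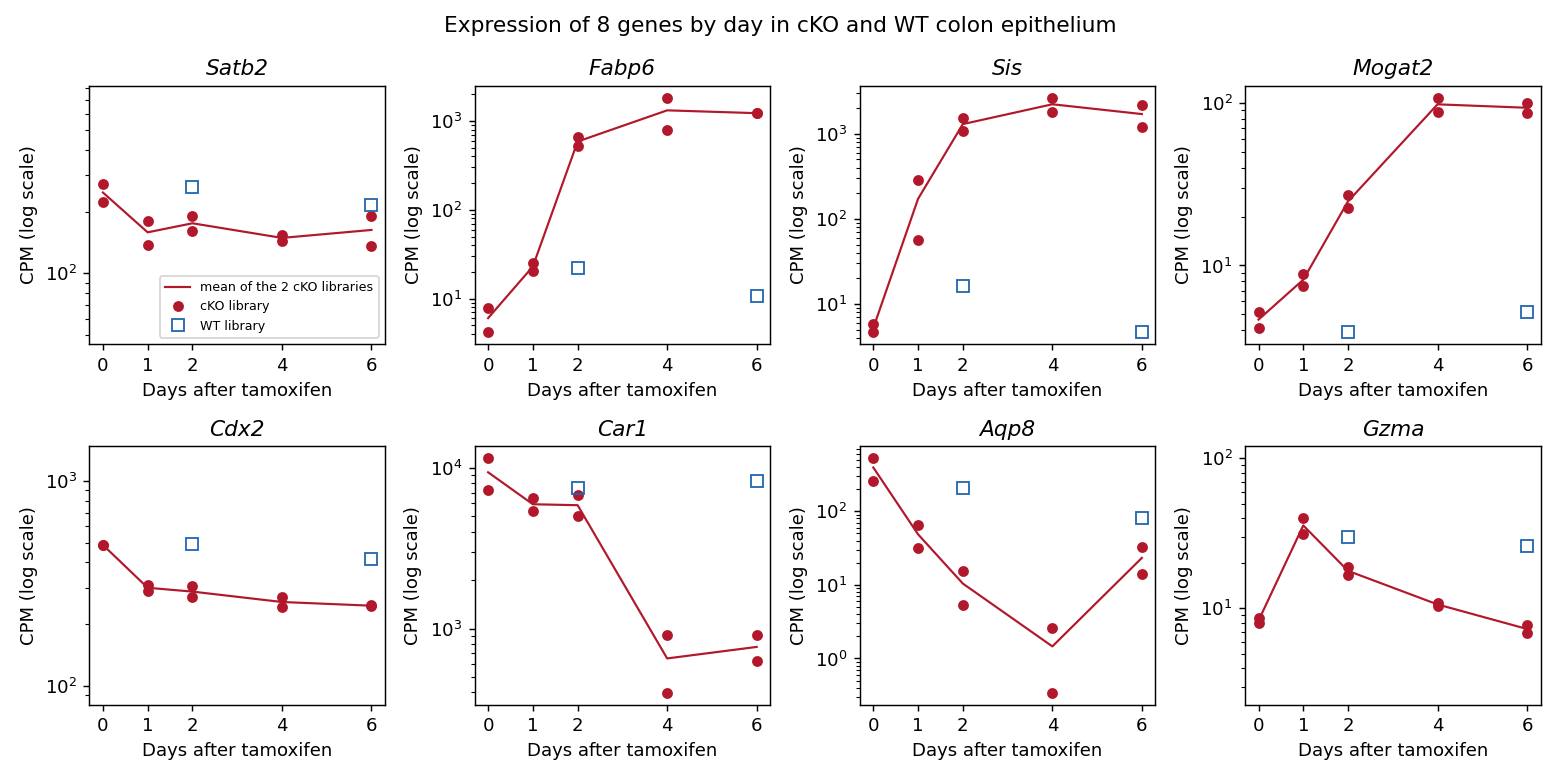
Expression of 8 genes (CPM on a log axis) by days after tamoxifen. Filled points are cKO libraries, the line joins the means of the 2 libraries of each day, and open squares are the single WT libraries.

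Libraries separated mainly by time after deletion. Over the 500 most variable genes the first principal component carried 53.6% of the variance. The Day 0 and WT libraries scored from -37.2 to -29.0 on it. The Day 1 libraries followed at -22.8 and -20.7, then the Day 2 libraries at 3.2 and 9.7. The Day 4 and Day 6 libraries scored from 32.7 to 42.8. Replicates of a group correlated at 0.9701 to 0.9767 across genes on log2 CPM, where genes are not independent replicates.

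The comparison of Day 1 with Day 0 asked what changed within a day of deletion. Genes of T cells and intraepithelial lymphocytes, which sit within the epithelium, were higher as a group. All 11 tested members were positive, with a median log2 fold change of 1.68 (camera adjusted p = 7.76e-25, adjusted p = 0.0119 with an estimated correlation). Gzma, a granzyme of cytotoxic lymphocytes, was the 1 gene that passed over all genes: it rose by 2.11 ± 0.19 on the log2 scale (SE), from 8.29 to 35.7 CPM (adjusted p = 0.0202). Adjusted over the list alone, 11 of the 11 members rose. The same genes were also higher in the WT libraries than on Day 0, as given below for that comparison.

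No epithelial gene passed over all genes on Day 1, though some differed widely in mean level. The colonocyte list, genes of the absorptive cells of the colon, was lower as a group (median -0.68, camera adjusted p = 1.78e-06, adjusted p = 0.308 with an estimated correlation). None of its 20 tested members passed over all genes, and 5 fell adjusted over the list alone. WT libraries, with intact Satb2, also lay below Day 0 in the colonocyte list. There 19 of 20 members were negative (median -0.40, camera adjusted p = 0.000181, adjusted p = 0.581 with an estimated correlation). Aqp8, a water channel, stood at 48.7 CPM against 395 (log2 -3.02 ± 0.72, adjusted p = 0.627). The ileal bile acid list was higher (median 0.45, camera adjusted p = 0.00293, adjusted p = 0.711 with an estimated correlation), with 0 of 6 members past the threshold over all genes and 1 that rose adjusted over the list alone. Fabp6, the ileal bile acid binding protein, stood at 23.0 CPM against 6.04 (log2 1.91 ± 0.40, adjusted p = 0.446). Sis, the sucrase-isomaltase of the small intestine, stood at 172 against 5.22 CPM (log2 5.04 ± 0.73, adjusted p = 0.146). Its list, the 17 brush-border genes, did not pass as a group (median 0.30, 10 positive and 7 negative, camera adjusted p = 0.885). None of them passed over all genes, and 2 rose and 1 fell adjusted over the list alone. The Paneth cell list was lower (median -1.61, or -1.53 with members at 0 set at their bound, camera adjusted p = 0.0306, adjusted p = 0.711 with an estimated correlation), and 0 of its 12 members passed, also adjusted over the list alone. The WT libraries lay below Day 0 in this list too (median -1.59, camera adjusted p = 0.0569). Beside edgeR's 1 call, 877 genes had an unadjusted p below 0.05, under the share of 0.05 that unchanged genes would give. DESeq2 called 43 genes and limma voom 1. With cKO libraries and a replicate block edgeR called 0, so Gzma was lost there too. Gzma lost its call without Day 0 replicate 1 or 2, Day 2 replicate 1 or 2, or Day 4 replicate 2, with only the Day 0 and Day 1 libraries, with the mean of the 3 control groups as the control (0 calls), and with the posterior Hox score as a covariate (0 calls). The number of calls was 2 without either Day 0 library, 6 without Day 1 replicate 1, 7 without Day 1 replicate 2, and 0 without either Day 2 library or Day 4 replicate 2.

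By Day 2, genes of small-intestinal absorption had risen and several colonocyte genes had fallen. Of 151 genes called against Day 0, 110 rose and 41 fell. Fabp6 rose from 6.04 ± 2.64 to 588 ± 99.8 CPM (SD, n = 2 each, log2 6.59 ± 0.47, adjusted p = 0.000871). Sis rose from 5.22 to 1300 CPM (7.95 ± 0.82, adjusted p = 0.00405). Slc16a1, a transporter of lactate and butyrate, fell by 1.24 ± 0.12 on the log2 scale (adjusted p = 0.00331).

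Among the bile acid genes, 3 of 6 rose over all genes and 6 adjusted over the list alone (median 2.56, camera adjusted p = 3.02e-11, adjusted p = 0.101 with an estimated correlation). Besides Fabp6 they were the apical transporter Slc10a2, from 124 to 705 CPM (2.51 ± 0.25), and the basolateral transporter subunit Slc51a (2.60 ± 0.35). Of the 17 lipid absorption genes, 5 rose over all genes, while adjusted over the list alone 7 rose and 1 fell (median 2.23, camera adjusted p = 5.21e-07, adjusted p = 0.452 with an estimated correlation). They included Mogat2, which resynthesizes diacylglycerol (2.42 ± 0.20, adjusted p = 0.00136), and Mttp, which loads lipid onto lipoproteins (5.79 ± 0.68). Of the 17 brush-border genes, 7 rose over all genes and 9 adjusted over the list alone (median 2.01, camera adjusted p = 1.99e-10, adjusted p = 0.313 with an estimated correlation), among them the peptidase Naaladl1 (4.99 ± 0.59) and the vitamin B12 receptor Cubn (5.08 ± 0.73). The sugar and amino acid transporters had 2 of 13 members that rose, and 4 adjusted over the list alone (median 0.65, camera adjusted p = 0.0033, adjusted p = 0.618 with an estimated correlation). Both were Slc13a1, a sulfate transporter (3.10 ± 0.41), and the amino acid transporter Slc7a9 (3.14 ± 0.59).

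Of the 20 colonocyte genes, 5 fell over all genes and 8 adjusted over the list alone (median -0.62, camera adjusted p = 6.02e-07, adjusted p = 0.146 with an estimated correlation). Besides Slc16a1 these included Aqp8, from 395 to 10.4 CPM (-5.22 ± 0.81), the anion exchanger Slc26a3 (-2.29 ± 0.31) and the water channel Aqp4 (-2.95 ± 0.53). Against the WT Day 2 library the median of the colonocyte list was -0.37, and the WT libraries themselves lay below Day 0 (median -0.40). Cdx2, a homeobox factor of intestinal identity, was the 1 of 20 transcription factors that passed, at 288 against 487 CPM (-0.76 ± 0.13, adjusted p = 0.0359). Adjusted over the list alone, 4 of the factors rose and 4 fell (camera adjusted p = 0.582). Among other strongly changed genes, Adh6a (an alcohol dehydrogenase, 7.15 ± 0.53), Lgals2 (a galectin, 6.31 ± 0.52) and Abcc2 (an organic anion pump, 6.09 ± 0.69) rose. Sult1a1 (a sulfotransferase, -3.62 ± 0.55) and Mal (an apical sorting protein, -3.50 ± 0.49) fell. The beta-defensin Defb39 had 0 counts on Day 0 and was at least 41.3-fold higher.

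T cell and intraepithelial lymphocyte genes were still higher on Day 2 (median 1.22, camera adjusted p = 4.23e-11, adjusted p = 0.0809 with an estimated correlation). Of the 11, Gzma (1.10 ± 0.19) and Cd3e (1.62 ± 0.29) rose, and 10 rose adjusted over the list alone. The rise was against the Day 0 libraries: with the mean of the 3 control groups as the control, Gzma changed to -0.07. Enteroendocrine genes were higher as a group (median 0.69, camera adjusted p = 6.02e-07, adjusted p = 0.101 with an estimated correlation), with 0 of 19 members called over all genes and 3 that rose adjusted over the list alone. Camera also called the erythroid list lower (5 genes, median -1.69, adjusted p = 0.0322, adjusted p = 0.618 with an estimated correlation). It called higher the goblet (14 genes, median 0.22, adjusted p = 0.0218, adjusted p = 0.378 with an estimated correlation), cell cycle (23, 0.27, adjusted p = 0.00177, adjusted p = 0.704 with an estimated correlation) and unfolded protein response lists (13, 0.21, adjusted p = 0.037, adjusted p = 0.618 with an estimated correlation). None of these 4 lists had a member called over all genes or adjusted over the list alone. The tuft cell list (11, 0.40, adjusted p = 0.00222, adjusted p = 0.452 with an estimated correlation) had 0 called and 1 that rose adjusted over the list alone. In the xenobiotic list (15, median 0.54, or 0.42 with members at 0 at their bound, adjusted p = 0.0124, adjusted p = 0.788 with an estimated correlation) 2 rose, and 2 adjusted over the list alone. Both Day 2 libraries were female and Day 0 held 1 of each sex. Of the 36 named calls on Day 2, 5 held with any 1 library left out (Adh6a, Fabp6, Lgals2, Mogat2 and Slc16a1). The 151 calls dropped to 39 without Day 0 replicate 1, 25 without Day 0 replicate 2, 25 without Day 2 replicate 1 (23 rose and 2 fell) and 48 without Day 2 replicate 2 (46 rose and 2 fell), and to 98 with sex as a covariate.

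Against the WT library of the same day, fewer genes were called on cKO Day 2, among them genes of bile acid and lipid handling. Of 22 genes called, 17 rose and 5 fell. Genes outside the lists are named by size, which the rule fixed beforehand did not cover for this comparison. Fabp6 (4.72 ± 0.58, adjusted p = 0.0254), Slc10a2 (2.53 ± 0.33), Mogat2 (2.68 ± 0.27), Lgals2 (5.01 ± 0.65) and Adh6a (6.08 ± 0.63) rose. Myrf, a membrane-bound transcription factor, rose from 0.24 to 18.3 CPM (6.22 ± 0.35, adjusted p = 0.00025), and Reg3a, a secreted antimicrobial lectin, from 1.04 to 66.5 CPM (5.99 ± 0.64, adjusted p = 0.0131). Slc16a1 (-1.27 ± 0.14) and Slc16a9 (-5.14 ± 0.70), both monocarboxylate transporters, and the adrenergic receptor Adra2a (-2.84 ± 0.35) fell. In this comparison 2 of 6 bile acid genes rose and 5 adjusted over the list alone (camera adjusted p = 3.89e-10, adjusted p = 0.381 with an estimated correlation). Of the lipid genes 1 of 17 rose, while 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.47e-06, adjusted p = 0.588 with an estimated correlation). Of the colonocyte genes 1 of 20 fell and 6 adjusted over the list alone (camera adjusted p = 0.0021, adjusted p = 0.548 with an estimated correlation). None of 17 brush-border genes passed over all genes and 9 rose adjusted over the list alone (median 2.49, camera adjusted p = 2.72e-08, adjusted p = 0.548 with an estimated correlation). None of 13 sugar and amino acid transporters passed and 2 rose adjusted over the list alone (median 0.79, camera adjusted p = 0.0016, adjusted p = 0.649 with an estimated correlation). Myeloid genes were higher too (median 1.61, 10 of 10 positive, camera adjusted p = 0.0016, adjusted p = 0.588 with an estimated correlation), with 0 called over all genes and 1 that rose adjusted over the list alone. The myeloid median was 1.48 with members at 0 at their bound. T cell and intraepithelial lymphocyte genes were not called against WT (median -0.17, 4 of 11 positive, camera adjusted p = 0.18), and none passed over all genes or adjusted over the list alone. Further lists were called higher by camera: enteroendocrine (median 0.74, adjusted p = 0.000372, adjusted p = 0.427 with an estimated correlation), antimicrobial and inflammatory (1.43, adjusted p = 0.000181, adjusted p = 0.588 with an estimated correlation), interferon and MHC class II (0.75, adjusted p = 0.00582, adjusted p = 0.711 with an estimated correlation), and unfolded protein response (0.51, adjusted p = 0.000649, adjusted p = 0.548 with an estimated correlation). So were immediate early and heat shock (0.48, adjusted p = 0.0207, adjusted p = 0.711 with an estimated correlation) and xenobiotic genes (1.05, or 0.44 with bounds, adjusted p = 0.0123, adjusted p = 0.711 with an estimated correlation), and Paneth genes were lower (-0.41, adjusted p = 0.0377, adjusted p = 0.588 with an estimated correlation). Among these 7 lists 1 xenobiotic gene rose over all genes, and adjusted over the list alone 2 xenobiotic genes and 1 enteroendocrine gene rose. All libraries of cKO Day 2 were female and the WT library male, and with sex as a covariate 1 call was left. The single WT library is assumed to vary like the other groups, and without Day 2 replicate 1 or 2 the count fell to 3 or 7, with 0 that fell in each (40 without either Day 1 library).

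On Day 4 the absorptive genes of the small intestine were among the largest changes. Of 843 genes called against Day 0, 450 rose and 393 fell. Anpep, a brush-border aminopeptidase, rose from 4.44 to 2000 CPM (8.82 ± 0.74, adjusted p = 0.000391), Sis to 2230 CPM (8.73 ± 0.84) and Fabp6 to 1320 CPM (7.75 ± 0.50). Car1, the carbonic anhydrase of the colon epithelium, fell from 9370 ± 2990 to 651 ± 359 CPM (SD, n = 2 each, -3.85 ± 0.43, adjusted p = 0.00134).

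Of the lipid absorption genes 14 of 17 rose, and 15 adjusted over the list alone (median 6.96, or 4.42 with members at 0 on Day 0 set at their bound, camera adjusted p = 2.12e-15, adjusted p = 0.258 with an estimated correlation). Mogat2 (4.41 ± 0.21, adjusted p = 3.65e-05), the cholesterol transporter Npc1l1 (7.38 ± 0.62) and Mttp (7.69 ± 0.73) were among them. Of the brush-border genes 11 of 17 rose, and 15 adjusted over the list alone (median 4.67, camera adjusted p = 3.78e-15, adjusted p = 0.258 with an estimated correlation). Bile acid genes rose in 4 of 6 cases and in 6 adjusted over the list alone (median 2.81, camera adjusted p = 3.94e-09, adjusted p = 0.217 with an estimated correlation). They now included Fgf15, the enterokine of the ileum, at 0 counts on Day 0 and at least 237-fold higher. Sugar and amino acid transporters rose in 7 of 13 cases and in 10 adjusted over the list alone (median 2.05, camera adjusted p = 9.91e-09, adjusted p = 0.316 with an estimated correlation). Xenobiotic genes rose in 4 of 15 cases and in 8 adjusted over the list alone (median 1.18, camera adjusted p = 0.00396, adjusted p = 0.674 with an estimated correlation), among them Gsta4 (2.06 ± 0.22). Reads of the Gsta and Cyp3a families may be split between near-identical copies.

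Colonocyte genes fell in 7 of 20 cases and in 11 adjusted over the list alone (median -1.10, camera adjusted p = 9.59e-09, adjusted p = 0.217 with an estimated correlation). Aqp8 dropped to 1.46 CPM (-8.18 ± 0.96), Sult1a1 to 1.70 CPM (-7.38 ± 0.69) and Mal to 4.19 CPM (-6.13 ± 0.57). The gasdermin C genes Gsdmc4 (-6.33 ± 0.67), Gsdmc3 (-5.70 ± 0.71) and Gsdmcl2 (-7.11 ± 0.82) fell together, and reads may be split between these paralogs too. Among transcription factors, Foxa1 (-1.04 ± 0.12), Cdx2 (-0.92 ± 0.13) and Hnf1b (adjusted p = 0.0228) fell. Creb3l3 (6.29 ± 1.05), Maf (3.79 ± 0.57), Gata5 (2.06 ± 0.32), Hnf4g (1.41 ± 0.26) and Gata6 (0.93 ± 0.16) rose. Adjusted over the list alone 6 of the 20 factors rose and 5 fell (camera adjusted p = 0.338). In the goblet list 2 of 14 rose and 3 adjusted over the list alone. They were the mucus protein Fcgbp (1.42 ± 0.24) and the trefoil factor Tff3 (1.38 ± 0.26), while the list as a group did not pass (camera adjusted p = 0.224). In the enteroendocrine list the hormones Cck (2.86 ± 0.37) and Sst (1.81 ± 0.33) rose, and 5 of 19 adjusted over the list alone (camera adjusted p = 0.00272, adjusted p = 0.281 with an estimated correlation). Cell cycle genes were higher as a group (median 0.43, camera adjusted p = 0.000644, adjusted p = 0.674 with an estimated correlation), and 0 of 23 passed over all genes or adjusted over the list alone.

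Markers of other cell types moved with these groups on Day 4. Fibroblast genes were higher (median 2.57, 7 of 7 positive, camera adjusted p = 0.00851, adjusted p = 0.664 with an estimated correlation), with 0 called over all genes and 3 that rose adjusted over the list alone. WT libraries lay above Day 0 in this list too (median 1.14, camera adjusted p = 0.0569), and the fibroblast gene Col1a1 differed widely between the Day 4 replicates. Myeloid genes were higher (median 1.09, camera adjusted p = 0.00398, adjusted p = 0.664 with an estimated correlation), where 1 of 10 rose over all genes (Lyz2, a lysozyme, 3.52 ± 0.65) and 3 adjusted over the list alone. Both Day 4 libraries were female, and the sex-linked list had a median of -12.23, or -8.52 with members at 0 at their bound. None of its 5 genes passed over all genes, and 4 fell adjusted over the list alone (camera adjusted p = 0.67). Of 59 named calls, 31 held with any 1 library left out, and the count dropped from 843 to 319 without Day 0 replicate 1, 276 without Day 0 replicate 2 and 457 without Day 4 replicate 1. Without Day 4 replicate 2, 519 rose and 244 fell. With sex as a covariate 534 genes were called, and 1282 with the mean of the 3 control groups as the control.

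On Day 6 the absorptive genes stayed high and the colonocyte genes low. Of 1016 genes called against Day 0, 502 rose and 514 fell. Fabp6 (chromosome 11, 43596049 to 43601540) stood at 1230 ± 5.33 against 6.04 ± 2.64 CPM (SD, n = 2 each, log2 7.65 ± 0.50, adjusted p = 0.000128). Sis (chromosome 3, 72888557 to 72967863) stood at 1710 ± 692 against 5.22 ± 0.81 CPM (8.35 ± 0.83, adjusted p = 0.0009). Car1 (chromosome 3, 14766216 to 14808368) stood at 768 ± 205 against 9370 ± 2990 CPM (-3.61 ± 0.42, adjusted p = 0.0018).

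Ileal bile acid genes rose in 4 of 6 cases and in 5 adjusted over the list alone (median 2.28, camera adjusted p = 3.88e-07, adjusted p = 0.382 with an estimated correlation). Besides Fabp6 these were Slc10a2 (2.51 ± 0.25), Slc51a (2.06 ± 0.34) and Fgf15, at least 70.7-fold higher. The remaining members, Slc51b (0.79 ± 0.26) and the bile acid receptor Nr1h4 (0.42 ± 0.20), did not pass. Lipid absorption genes rose in 11 of 17 cases and in 15 adjusted over the list alone (median 6.18, or 4.34 with members at 0 at their bound, camera adjusted p = 2.27e-11, adjusted p = 0.416 with an estimated correlation). Mogat2 stood at 93.5 against 4.64 CPM (4.34 ± 0.21, adjusted p = 4.12e-05), and Mttp (7.32 ± 0.72), Npc1l1 (6.88 ± 0.61) and the sterol exporter Abcg5 (6.44 ± 0.71) rose with it. Brush-border genes rose in 11 of 17 cases, while 12 rose and 1 fell adjusted over the list alone (median 4.12, camera adjusted p = 5.53e-10, adjusted p = 0.416 with an estimated correlation). Anpep (7.64 ± 0.70), Naaladl1 (6.23 ± 0.63) and Ace2 (4.12 ± 0.50) were among them. Sugar and amino acid transporters rose in 5 of 13 cases and in 8 adjusted over the list alone (median 1.49, camera adjusted p = 0.000126, adjusted p = 0.506 with an estimated correlation), such as Slc13a1 (3.08 ± 0.41) and the amino acid transporter Slc7a9 (3.44 ± 0.60).

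Colonocyte genes fell in 10 of 20 cases and in 15 adjusted over the list alone (median -1.45, camera adjusted p = 4.83e-09, adjusted p = 0.311 with an estimated correlation). They included Slc16a1 (-0.92 ± 0.12), the selenium-binding protein Selenbp1 (-2.06 ± 0.31) and the adhesion molecule Ceacam1 (-1.09 ± 0.17). Outside the lists, Sult1a1 (-6.32 ± 0.64), Mal (-5.51 ± 0.55), Slc16a9 (-5.53 ± 0.69), the lipid transporter Abca12 (-5.34 ± 0.70) and the lactoperoxidase Lpo (-4.11 ± 0.27, adjusted p = 0.000131) were among those that fell most. Adh6a (8.96 ± 0.54, adjusted p = 8.53e-05) and Lgals2 (8.23 ± 0.56) were among those that rose most. Cfhr2, a complement factor H relative, had 0 counts on Day 0 and was at least 175-fold higher. Fam20a was at least 73.3-fold and Oas1f at least 51.2-fold higher by the same rule.

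Of 20 intestinal transcription factors 5 rose and 3 fell, and 5 rose and 5 fell adjusted over the list alone, so the list had no direction as a group (camera adjusted p = 0.733). Cdx2 (chromosome 5, 147300805 to 147307270) stood at 246 ± 1.94 against 487 ± 2.10 CPM (SD, n = 2 each, -0.98 ± 0.13, adjusted p = 0.00305). Foxa1 (-0.99 ± 0.12) and Hnf1b (-1.32 ± 0.20) fell with it. Creb3l3 (5.82 ± 1.04), Maf (3.23 ± 0.56), Gata5 (1.31 ± 0.31), Hnf4g (1.19 ± 0.26) and Gata6 (0.94 ± 0.16) rose. Hnf4a differed by 0.15 ± 0.15 and Gata4 by 1.49 ± 0.86, and neither passed. None of 11 Hox genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.713).

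Secretory and crypt groups moved in parts. Of 14 goblet genes Fcgbp (1.16 ± 0.24) and Tff3 (1.13 ± 0.26) rose and Kit (-0.96 ± 0.21) fell, and adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.876). Of 19 stem cell and Wnt genes 3 rose, such as Smoc2 (1.23 ± 0.20), and 2 fell, such as Prom1 (-1.57 ± 0.22), with 5 and 2 adjusted over the list alone (camera adjusted p = 0.876). Of 23 cell cycle genes 22 were positive, 1 rose (Mcm7, 0.79 ± 0.17) and 2 rose adjusted over the list alone (median 0.59, camera adjusted p = 1.84e-05, adjusted p = 0.506 with an estimated correlation). Of 19 enteroendocrine genes 4 rose and 2 fell, with 7 and 3 adjusted over the list alone (median 0.50, camera adjusted p = 0.0218, adjusted p = 0.444 with an estimated correlation). Cck rose by 3.60 ± 0.38 (adjusted p = 0.00117), and Sst (1.87 ± 0.33), Arx (2.95 ± 0.50) and Isl1 (2.54 ± 0.54) rose with it. Of 11 tuft cell genes 1 rose (Ptgs1, 1.92 ± 0.35) and 3 adjusted over the list alone (median 0.67, camera adjusted p = 0.00118, adjusted p = 0.444 with an estimated correlation). Of 12 Paneth genes Defa22, at 46 counts on Day 0 and 0 on Day 6, and Nupr1 (-1.57 ± 0.38) fell, and 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0564). Defensin reads may be split between paralogs.

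Stress, defence and detoxification lists had up to 2 members called each. Of 15 interferon and MHC class II genes H2-Eb1 (-0.93 ± 0.19) and H2-Aa (adjusted p = 0.031) fell, and 4 fell adjusted over the list alone (median -0.73, camera adjusted p = 0.00389, adjusted p = 0.640 with an estimated correlation). Of 15 xenobiotic genes Gsta4 (2.79 ± 0.23) and Gsta1 (3.38 ± 0.44) rose, and 7 rose and 1 fell adjusted over the list alone (median 1.15, camera adjusted p = 0.00345, adjusted p = 0.640 with an estimated correlation). Of 13 unfolded protein response genes Trib3 (3.12 ± 0.61) and Atf4 (0.61 ± 0.12) rose, and 2 adjusted over the list alone (median 0.31, camera adjusted p = 0.0198, adjusted p = 0.506 with an estimated correlation). Of 12 p53 targets Trp53inp1 fell (-2.22 ± 0.28), and 1 adjusted over the list alone (camera adjusted p = 0.964). None of 17 epithelial antimicrobial genes passed, also adjusted over the list alone (camera adjusted p = 0.268). The same held for 13 immediate early and heat shock genes (camera adjusted p = 0.733).

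Markers of cells other than epithelium gave these Day 6 values. T cell and intraepithelial lymphocyte genes were lower (median -0.55, camera adjusted p = 0.0233, adjusted p = 0.444 with an estimated correlation): Lck (-1.24 ± 0.26) and Cd8a (-1.10 ± 0.24) fell, and 2 of 11 adjusted over the list alone. Fibroblast genes were higher (median 2.60, 7 of 7 positive, camera adjusted p = 0.00345, adjusted p = 0.506 with an estimated correlation), with 0 called over all genes and 3 that rose adjusted over the list alone. Col1a1 again differed widely between replicates, and the WT median against Day 0 was 1.14. The lists of B and plasma cells (9 tested, median -1.74, camera adjusted p = 0.0564), myeloid cells (10, 0.64, 0.09), smooth muscle (6, 0.20, 0.876), endothelium (2, 0.15, 0.876), enteric neurons and glia (3, -0.51, 0.722), erythroid cells (5, 0.21, 0.733) and sex-linked genes (5, 0.27, 0.268) had no member past the threshold over all genes or adjusted over the list alone. Median, mean and test direction differed in sign on Day 6 for the goblet, stem cell and Wnt, p53, smooth muscle and sex-linked lists, and none of these passed.

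**Figure D2:**
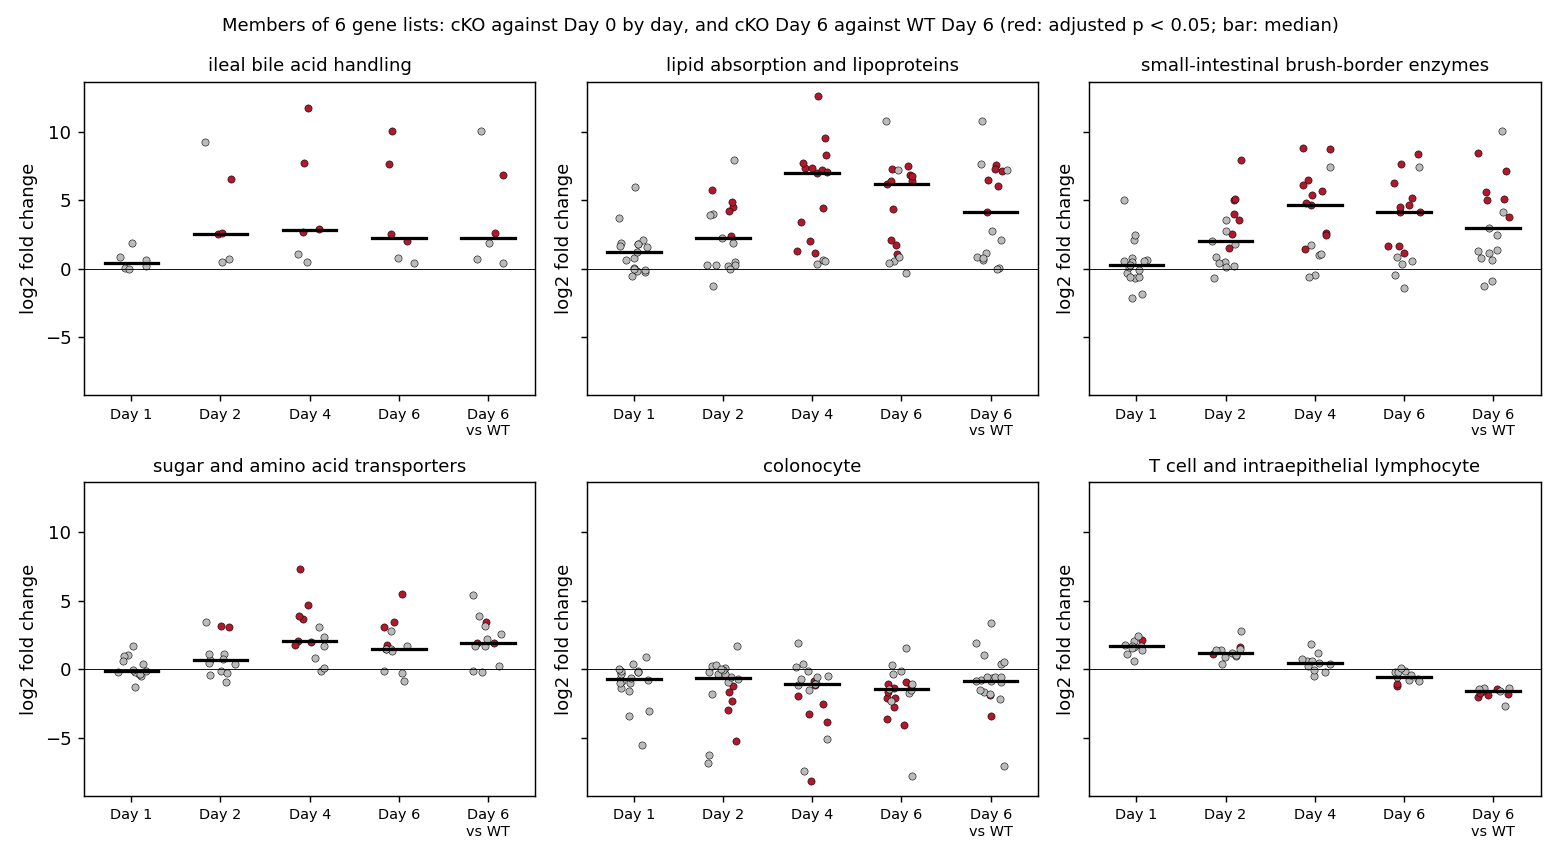
Log2 fold change of each tested member of 6 gene lists, for cKO Day 1, 2, 4 and 6 against Day 0 and for cKO Day 6 against WT Day 6. Each point is a gene, red where the edgeR adjusted p passed, and the bar is the list's median.

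Over the list tests, camera with its preset correlation called 13 of 28 lists on Day 6 against Day 0, and none passed with an estimated correlation (smallest adjusted p = 0.311). Over all comparisons with lists, the calls that held with an estimated correlation were those of the T cell and intraepithelial lymphocyte list on Day 1 and in WT, both against Day 0. Fry, which tests whether a list moved on balance without comparing it with other genes, called 5 lists: bile acid, lipid, brush-border, colonocyte and enteroendocrine. Of the 70 named calls on Day 6, 36 held with any 1 library left out, including Fabp6, Sis, Mogat2, Anpep, Car1, Slc16a1, Cdx2, Foxa1 and Cck. Those that did not hold included Fgf15, Slc51a, Creb3l3, Maf, Gata5, Gata6, Hnf4g, Fcgbp and Tff3. The count fell from 1016 to 371 without Day 0 replicate 1, 313 without Day 0 replicate 2 and 537 without Day 6 replicate 1, and to 573 with the posterior Hox score as a covariate.

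Compared with the WT library of Day 6, which had received tamoxifen too, the cKO Day 6 libraries showed the absorptive genes higher and colonocyte genes lower. Of 345 genes called, 178 rose and 167 fell. Fabp6 stood at 1230 against 10.8 CPM (6.83 ± 0.65, adjusted p = 0.00234), Mogat2 at 93.5 against 5.14 CPM (4.18 ± 0.28, adjusted p = 0.000501) and Sis at 1710 against 4.76 CPM (8.49 ± 1.15, adjusted p = 0.00943). Car1 stood at 768 against 8240 CPM (-3.42 ± 0.46, adjusted p = 0.00879). Cdx2 (-0.76 ± 0.15, adjusted p = 0.0429) and Foxa1 (-0.98 ± 0.14) fell.

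The lists gave 2 of 6 bile acid genes that rose and 4 adjusted over the list alone (median 2.24, camera adjusted p = 1.05e-07, adjusted p = 0.206 with an estimated correlation). Lipid genes rose in 6 of 17 cases and in 15 adjusted over the list alone (median 4.18, or 3.03 with members at 0 at their bound, camera adjusted p = 1.87e-12, adjusted p = 0.206 with an estimated correlation). Brush-border genes rose in 6 of 17 cases and in 13 adjusted over the list alone (median 3.00, camera adjusted p = 7.07e-12, adjusted p = 0.206 with an estimated correlation). Colonocyte genes fell in 2 of 20 cases, while 7 fell and 1 rose adjusted over the list alone (median -0.82, camera adjusted p = 0.000261, adjusted p = 0.206 with an estimated correlation). Among genes outside the lists, Lgals2 (7.74 ± 0.75), Rbp2, a retinol-binding protein (7.70 ± 0.87), and Abcc2 (8.28 ± 1.01) rose, and Sult1a1 (-5.57 ± 0.65), Mal (-5.35 ± 0.57) and Slc16a9 (-5.67 ± 0.73) fell. Fcgbp (1.88 ± 0.32) and Tff3 (1.67 ± 0.34) were 2 of 14 that rose in the goblet list, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.477). Xenobiotic genes such as Gsta4 (3.61 ± 0.32) rose in 2 of 15 cases and in 6 adjusted over the list alone (camera adjusted p = 3.85e-05, adjusted p = 0.507 with an estimated correlation). Sugar and amino acid transporters rose in 3 of 13 cases and in 9 adjusted over the list alone (median 1.95, camera adjusted p = 2.55e-06, adjusted p = 0.329 with an estimated correlation). Tuft cell (median 0.62, camera adjusted p = 0.000176, adjusted p = 0.329 with an estimated correlation) and unfolded protein response genes (0.34, camera adjusted p = 0.0102, adjusted p = 0.507 with an estimated correlation) were higher with 0 called, and 0 and 1 rose adjusted over the list alone. Several lists called against Day 0 were not called against WT: cell cycle (median 0.06, camera adjusted p = 0.814), enteroendocrine (-0.03, camera adjusted p = 0.294), interferon and MHC class II (-0.56, camera adjusted p = 0.0967) and fibroblast (1.17, camera adjusted p = 0.392). In the enteroendocrine list 2 rose and 1 fell, with 6 and 3 adjusted over the list alone, and the other 3 had none of either. The Paneth list had a median of 0.78, or 0 with bounds (camera adjusted p = 0.683), with 0 called over all genes, 1 that rose and 2 that fell adjusted over the list alone. The WT Day 6 library held 0 defensin counts.

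Lymphocyte genes were lower in cKO than in WT on Day 6. T cell and intraepithelial lymphocyte genes fell in 6 of 11 cases and in 11 adjusted over the list alone (median -1.60, camera adjusted p = 6.52e-11, adjusted p = 0.0862 with an estimated correlation), such as Gzma (-1.84 ± 0.22, adjusted p = 0.00533). B and plasma cell genes fell in 1 of 9 cases and in 4 adjusted over the list alone (median -2.71, camera adjusted p = 4.92e-05, adjusted p = 0.382 with an estimated correlation). The 1 gene was Ms4a1, at 0.224 against 9.41 CPM (-5.30 ± 1.00). None of 11 Hox genes passed over all genes, while 5 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.952). The mean log2 CPM of 5 posterior Hox genes was 0.73 in the WT Day 6 library, the lowest of the 12, and 4.86 and 3.61 in the Day 6 libraries. With that score as a covariate 14 of the 345 calls were left in number (12 higher and 2 lower), and 5 of the 50 named calls held. With 1 WT library there is no replicate check on that side, and 118 genes were called without Day 6 replicate 1, 214 without Day 2 replicate 2 and 228 without Day 2 replicate 1.

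The WT libraries and uninjected cKO libraries, the study's pair of controls, differed in lymphocyte genes, the list with the smallest camera p. The T cell and intraepithelial lymphocyte list was higher in WT by a median of 1.08 (11 of 11 positive, camera adjusted p = 5.57e-18, adjusted p = 0.0255 with an estimated correlation). Adjusted over the list alone 9 of its 11 members rose, and none over all genes. Gzma stood at 28.0 against 8.29 CPM (1.76 ± 0.19, adjusted p = 0.0895). Camera also called the colonocyte list lower (median -0.40, adjusted p = 0.000181, adjusted p = 0.581 with an estimated correlation) and the cell cycle list higher (median 0.28, adjusted p = 6.9e-06, adjusted p = 0.634 with an estimated correlation). The stem cell and Wnt list (median 0.21, adjusted p = 0.00952, adjusted p = 0.725 with an estimated correlation) and the tuft cell list (median 0.27, adjusted p = 0.0115, adjusted p = 0.634 with an estimated correlation) were called higher too. In none of these 4 lists did a member pass over all genes or adjusted over the list alone. Larger medians that did not pass were those of Paneth cells (-1.59, camera adjusted p = 0.0569), fibroblasts (1.14, camera adjusted p = 0.0569) and enteric neurons and glia (-3.52 over 3 genes, camera adjusted p = 0.312). An unadjusted p below 0.05 was found for 738 genes, under 0.05 of those tested, and DESeq2 called 11 and limma voom 0. The edgeR test called 0 genes. It called 2 without either Day 0 library. Satb2 differed by -0.06 ± 0.20.

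Between consecutive days, the genes called changed between Day 1 and Day 4, named here by the same rule of size after the values were seen. From Day 1 to Day 2, 967 genes had an unadjusted p below 0.05, little over 0.05 of those tested, and DESeq2 called 29 lower. By edgeR 23 genes rose and 0 fell. Fabp6 (4.67 ± 0.43, adjusted p = 0.0103), Slc10a2 (1.83 ± 0.24), Mogat2 (1.60 ± 0.19) and S100g, an intestinal calcium-binding protein (4.22 ± 0.55), were among them. From Day 2 to Day 4, 8 rose and 8 fell. Anpep (4.83 ± 0.60, adjusted p = 0.0263), Mogat2 (1.98 ± 0.19), Myrf (1.99 ± 0.18) and Tm4sf5, a tetraspanin-like membrane protein (2.68 ± 0.21), rose, and Car1 (-3.17 ± 0.41, adjusted p = 0.0329) and Lpo (-2.21 ± 0.25) fell. From Day 4 to Day 6 edgeR called 0 genes, DESeq2 11 and limma voom 0. An unadjusted p below 0.05 was found for 693 genes, under 0.05 of those tested. The Day 1 to Day 2 count moved to 1 without Day 1 replicate 1 or Day 2 replicate 1, 12 without Day 1 replicate 2, 8 without Day 2 replicate 2, and 44 or 43 without Day 4 replicate 1 or 2. Day 1 held both sexes and Day 2 females only, and with sex as a covariate 3 of the 23 calls were left in number and 2 of the 12 named calls held. With cKO libraries and a replicate block 9 calls were left. The Day 2 to Day 4 count moved to 0 or 1 without Day 2 replicate 1 or 2, 25 without Day 1 replicate 1 and 56 without Day 4 replicate 2. Over the 5 cKO days together, 804 genes changed, and 419 or 401 without Day 0 replicate 1 or 2 and 490 with the posterior Hox score as a covariate.

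The day-by-day gene sets overlapped. Of the Day 2 calls against Day 0, 107 that rose and 40 that fell did the same on Day 4, against 2.8 and 0.9 for independent lists. In 20 simulated draws with unchanged groups the means were 0 and 0. There every cKO library, Day 0 included, was drawn anew from the Day 0 mean, so the comparisons shared drawn Day 0 libraries, not the real ones. Day 4 and Day 6 shared 361 that rose and 312 that fell (12.7 and 11.3 for independent lists, 0 and 0.05 simulated). Fold changes on Day 4 and Day 6 correlated at 0.81 across genes, against 0.53 simulated, with a covariance of 1.18 against 0.27. Their 673 shared calls became 267 or 231 without Day 0 replicate 1 or 2, 437 without Day 4 replicate 1 and 426 without Day 6 replicate 1, 378 with sex and 435 with the posterior Hox score as a covariate. The simulated counts leave out real effects and the independent ones leave out the shared controls, so the excess over either is not read as a shared effect. Controls cannot be split with 2 libraries in each part, so part of the excess may come from the shared Day 0 libraries. In comparisons whose groups share no library, Day 2 against Day 0 and Day 6 against WT Day 6, 75 genes rose in both and 24 fell in both (1.1 and 0.4 for independent lists), and 2 went opposite ways. The spread behind both was still estimated over all libraries together. The 99 shared calls became 31 or 19 without Day 0 replicate 1 or 2 and 23 or 37 without Day 2 replicate 1 or 2, and 11 with the posterior Hox score as a covariate. Day 4 against Day 0 and Day 6 against WT Day 6 shared 161 that rose and 116 that fell (4.5 and 3.7), and 0 went opposite ways.

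The Day 2 to Day 6 change was also set against that of the WT libraries. Tm4sf5 was the 1 gene called: it went from 10.1 and 11.1 CPM on Day 2 to 112 and 83.6 on Day 6 in cKO, and from 6.83 to 3.56 CPM in WT (difference of log2 changes 4.14 ± 0.38, edgeR adjusted p = 0.0227, named after its value was seen). Beside it 995 genes had an unadjusted p below 0.05, little over 0.05 of those tested, DESeq2 called 50 and limma voom 0. The call rests on 1 WT library per day. It was lost without any 1 of the Day 0, Day 1 and Day 2 libraries (0 calls each), and 2 genes were called without any 1 of the Day 4 and Day 6 libraries. The cKO Day 2 libraries were female and the cKO Day 6 and WT libraries male. With sex as a covariate the difference was 4.35 ± 0.44 (adjusted p = 0.12), and with the posterior Hox score 3.86 ± 0.52 (adjusted p = 0.765), so 0 genes were called with either.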

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

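The Tm4sf5 result comes from a planned contrast. All tests that weigh explanations below were chosen after the results were seen.

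Tm4sf5 stood apart because its change from Day 2 to Day 6 differed between cKO and WT by 4.14 on the log2 scale (edgeR adjusted p = 0.0227), with 2 cKO libraries and 1 WT library per day. With sex as a covariate it was 4.35 ± 0.44 (SE, against 0.38 without) and with the posterior Hox score 3.86 ± 0.52. The call ended with either (adjusted p = 0.12 and 0.765), where the SE was wider and, with the Hox score, the difference smaller. Its cause stays open.

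For the rise of absorptive genes and fall of colonocyte genes on Day 4 and Day 6, admixed small-intestinal tissue would bring Paneth cell defensins, yet their mean was 0.34 CPM on Day 4 and Day 6 against 5.48 on Day 0, which argues against tissue that includes crypts. Dilution by other tissue would lower colon transcripts by no more than Satb2. Of the 514 genes called lower on Day 6, 207 (40.3%) fell beyond it with 2 SE allowed on each side. Dilution alone would not give falls of that size in these 207 genes. The share itself carries no weight, as falls as small as that of Satb2 (log2 -0.61, not called) seldom enter the set. Of the 41 members of these lists called on Day 6, 19 were called the same way against the WT Day 6 library, which had the same sex. All 41 kept their direction there. Colonocyte genes made up 10 of the 41 calls and 2 of the 19. With the posterior Hox score as a covariate, 31 of the 41 stayed called. For the falls the comparison within 1 sex rests on 2 calls. Sex alone would move Day 4, all female, and Day 6, all male, in opposite directions from Day 0, which held both. Yet the colonocyte medians were -1.10 and -1.45, and 0 of the genes called on both days went opposite ways. These values argue against sex as the cause of the changes that both days share. A trend along the Hox score may not be the cause of all of it. With that covariate, 2 of the 19 stayed called against the WT Day 6 library, which had the lowest score, as their median size went from 5.13 to 4.72 and their median SE from 0.77 to 0.93. Part of the colonocyte fall against Day 0 was also seen with intact Satb2: the list median was -0.40 in WT, against -1.45 on cKO Day 6. A response to the loss of Satb2 stays a hypothesis, and villus tissue without crypts, or a sampling position that the Hox score does not follow, stay open.

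T cell and intraepithelial lymphocyte genes were higher on Day 1 than on Day 0. Loss of Satb2 as the only cause is argued against by the WT libraries, which were higher than Day 0 too, with a median of 1.08 on the log2 scale. Yet cKO Day 1 lay above the mean of WT Day 2 and WT Day 6 (median 0.35, 10 of 11 positive, camera p = 3.21e-06, p = 0.0155 with an estimated correlation, both unadjusted). No WT library was from Day 1, and on Day 2 cKO did not lie above WT (median -0.17, 4 of 11 positive). A part of Satb2 loss in the rise stays open. Sex is argued against by the balance of the groups, as Day 0 and Day 1 each held a female and a male library. For the same reason a covariate for sex could hardly move the comparison (median 1.71, 11 of 11 positive), and it adds no support. Injection and handling may be a source, as WT Day 2 (median 1.39) and WT Day 6 (0.97) both lay above Day 0, but cKO Day 6 did not (-0.55), and no uninjected WT or injected Day 0 library separates the 2. The share of lymphocytes left in each preparation cannot be told apart from a change in the tissue, since no cell count goes with these libraries.

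Satb2 mRNA in injected cKO libraries was at 66.2% of the controls rather than near 0. Cells that kept Satb2 in equal share among all cell types would cap every other fall at that of Satb2. On Day 6, 207 genes fell beyond it with 2 SE allowed on each side. They come from the 514 genes called lower, a set picked for large falls (median log2 -1.29), so their share carries no weight. Under that cap, the falls of these 207 genes argue against such cells as the only reason for the 66.2%. Transcripts from exons outside the deleted part cannot be told apart here, as counts per exon were not analysed here. The values therefore give no figure for the share of cells with the deletion.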

How the results depend on the processing

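The alternatives with sex, the Hox score or without genes of other cell types were chosen after the data were seen, and the rest before. Values that moved by more than 1.5 times are given here, and the cause was not tested unless fewer libraries or other genes tested give it. DESeq2 called 43, 425, 1388 and 1662 genes on Day 1, 2, 4 and 6 against Day 0. It called 250 and 881 on Day 2 and Day 6 against WT, 11 for WT against Day 0, 166, 237 and 11 between consecutive days, 50 for the difference from WT and 1868 over the cKO days. Its shared calls were 1089 for Day 4 with Day 6, and 267 for Day 2 with Day 6 against WT. Without a filter on low counts (30679 genes tested) these numbers were 350, 838, 1988 and 2409, then 615 and 1538, 215, then 508, 707 and 243, 425, 3096, 1552 and 474. Of the 1414 genes called on Day 6 without the filter alone, 218 had a mean CPM under 1.

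With cKO libraries and the replicate block, Day 1 gave 0 calls and Day 1 to Day 2 gave 9, and the block changed no other count by over 1.5 times (121, 788 and 1003 on Day 2, 4 and 6). The numbers were not taken as a pairing, since no label ties them and 3 of 10 correlations between pairs of groups were above 0.1 (-0.10 to 0.18). As hints from the data, 4 of 5 libraries numbered 1 were closest to another numbered 1, and in all 5 groups number 1 had fewer counts and lay higher on the second principal component, so a shared step is not excluded. With the mean of the 3 control groups as the control, Day 1 gave 0 and Day 4 gave 1282 calls. With both WT libraries as the control, Day 2 gave 104 and Day 6 gave 943. With only the groups compared, Day 2 gave 268, Day 4 gave 556 and Day 4 to Day 6 gave 3. Limma voom gave 0 for the difference from WT. With sex as a covariate, Day 2 gave 98, Day 4 534, Day 2 against WT 1, Day 1 to Day 2 3, the difference from WT 0 and Day 4 with Day 6 378. With the posterior Hox score, Day 1 gave 0, Day 6 573, Day 6 against WT 14, the difference from WT 0, the cKO days 490, Day 4 with Day 6 435 and Day 2 with Day 6 against WT 11. Without genes of other cell types, Day 1 gave 0, as Gzma was left out by construction.

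With each library left out in turn, counts ranged from 0 to 7 on Day 1, 25 to 188 on Day 2, 276 to 856 on Day 4 and 313 to 1149 on Day 6. They ranged from 3 to 40 for Day 2 and 118 to 450 for Day 6 against WT, 0 to 2 for WT against Day 0, 1 to 44, 0 to 56 and 0 to 0 between consecutive days, 0 to 2 for the difference from WT and 401 to 864 over the cKO days. Shared calls ranged from 231 to 675 for Day 4 with Day 6 (main 673) and from 19 to 126 for Day 2 with Day 6 against WT (main 99). The lowest values of Day 2, Day 4, Day 6 and the cKO days were those without Day 0 replicate 2, for Day 2 also without Day 2 replicate 1. Comparisons with a lone WT library cannot be run without it.

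Reversals were few. Gzma changed to -0.07 on Day 2 and -0.81 on Day 4 with the mean of the 3 control groups as the control, and the sex-linked list to -0.87 on Day 6 with sex as a covariate. Of 19872 values of named genes under 16 other alternatives, 19023 kept their side of the threshold, and their direction where called. Of the rest, 293 lost and 554 gained a call, and 2 reversed. With a library left out, 17224 of 17852 were kept, 570 lost and 58 gained. Genes not called in the main fit are among these values and count as kept while uncalled. Of the named calls alone, 5 of 36 on Day 2 held with any 1 library left out. The numbers were 31 of 59 on Day 4, 36 of 70 on Day 6 and 23 of 50 on Day 6 against WT. For the lists on Day 6, 286 of 324 values were kept, 26 lost, 11 gained and 1 reversed, and 310 of 336 with a library left out. Lists that stayed uncalled count as kept here too, and all 13 lists called by camera lost their call with an estimated correlation. Without Day 4 replicate 2, 68.0% of the Day 4 calls were higher, against 53.4%, and without Day 2 replicate 1 or 2, 92.0% or 95.8% of the Day 2 calls, against 72.8%. Depth limits the weakly expressed genes: a gene with 0 counts on Day 0 has only a lower bound for its fold.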

Other observations

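All tests in this part were chosen after the data were seen, and no explanation was weighed here.

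Krt84, a hair-type keratin, stood highest on Day 2, at 78.4 and 75.0 CPM against 10.4 and 4.15 on Day 0, 3.15 and 7.23 on Day 1, 40.5 and 47.1 on Day 4, 36.8 and 37.4 on Day 6, and 3.71 and 2.68 in the WT libraries. Reg3a held 2.29 and 1.64 CPM on Day 0, 3.73 and 5.21 on Day 1, 89.3 and 43.7 on Day 2, 42.5 and 60.7 on Day 4, 36.9 and 24.2 on Day 6, and 1.04 and 2.47 in the WT libraries. The interferon-induced genes Isg15 and Ifit1 were high in single libraries: Isg15 at 132 CPM in Day 2 replicate 1 and 117 in Day 4 replicate 1 against 56.6 and 25.1 in their replicates, and Ifit1 at 206 and 185 CPM against 82.4 and 33.9.

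The 345 genes called between cKO Day 6 and WT Day 6 were followed back in libraries outside the groups compared. Those libraries still entered the shared estimate of spread, so they helped decide which genes were called. On Day 1 against Day 0, 140 of the 178 higher genes were positive (median 0.32, camera p = 9.13e-14, p = 0.0824 with an estimated correlation) and 114 of the 167 lower genes negative (median -0.23, camera p = 1.17e-09, p = 0.00825 with an estimated correlation). On Day 2 the medians were 1.41 and -0.59 (camera p = 0.00202 and 0.000312 with an estimated correlation), and on Day 4 they were 2.19 and -1.45 (p = 0.00124 and 5.39e-05). In WT Day 2 against Day 0 they were 0.05 and 0.04 (camera with an estimated correlation, p = 0.69 and 0.488). All of these lie on the same Day 0 libraries, so they are not independent of each other. In cKO Day 1 against WT Day 2, without Day 0, the medians were 0.24 and -0.23 (camera with an estimated correlation, p = 0.165 and 0.00636).

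Libraries also differed in cells other than epithelium. Mean log2 CPM of the T cell and intraepithelial lymphocyte list was 1.7 and 2.04 on Day 0, 3.52 and 3.44 on Day 1, 1.2 and 1.49 on Day 6, and 3.2 and 3.03 in WT. The fibroblast gene Col1a1 held 18.6 CPM in Day 4 replicate 2 and 17.1 in Day 6 replicate 1 against 1.64 and 3.33 in their replicates. Ms4a1 and Cd19 of B cells held 9.41 and 7.79 CPM in WT Day 6. The posterior Hox score ran from 0.73 in WT Day 6 and 1.54 in Day 0 replicate 2 to 4.86 in Day 6 replicate 1. Paneth cell defensin counts were 74 and 124 on Day 0, 118 in WT Day 2 and 0 in WT Day 6.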
